A study of Oryza sativa with 4 samples.

How the data were processed

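Developing endosperm of rice (Oryza sativa) was profiled in the cultivar Nipponbare and in NIL(TGW6), a near-isogenic line that carries the grain weight locus qTGW6, at 3 and 6 DAH. DAH is the abbreviation of the sample titles, and other labels of the same samples count the days from flowering. Total RNA of both lines was hybridised together on each of 4 Agilent rice arrays of the 2-colour type, with 2 arrays per stage. NIL(TGW6) was in the Cy5 channel on replicate 1 and in the Cy3 channel on replicate 2 of each stage, so the dyes were swapped within a stage. The labelling text of the samples describes a procedure for Cy3 alone, whereas the files hold 2 channels, and the channel labels were followed here. The labels do not state whether the 2 arrays of a stage hold separate extracts. P-values of single genes therefore measure the spread between arrays, which may be technical. Over both stages they measure the spread between the 2 stage means instead. P-values of gene lists measure the spread over genes at an assumed or estimated correlation. Those for shares of calls on chromosome 6 treat genes as independent, which they are not. Counts of genes at least 2-fold apart are given beside the p-values. The file headers show 1 slide and 1 scan date for the 4 arrays.

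Per the file headers, the images were extracted with Agilent Feature Extraction 9.5.3.1, and the deposited scanner files give the mean spot signal and the median local background of each channel as linear intensity. The same deposited files give processed intensity values, from which the software had subtracted background and removed spatial trends and dye bias, and their ratio as log10 of red over green. The deposited series matrix holds log10 ratios of red over green. It was set against the scanner files and differed from their log ratio by at most 5e-10, with between 6652 and 7210 blank values per array. No genome build is stated, and genes are identified by the locus ID in each probe name and by the description that the files pair with it. Chromosome numbers were read from the locus IDs, and no coordinates were used.

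Each array held 45151 spots, of which 42124 were gene probes with a locus ID and 1417 were controls. A further 1610 probe spots without a locus ID were not used in the comparisons. The median mean signal per channel ranged from 286.5 to 670.5, the median local background from 46 to 60, and between 72.75% and 76.34% of probe spots per channel were well above background by the software's test. Spots marked as outliers by the software were set aside on that array, and 0 spots were saturated. The number of arrays limits the precision: the median standard error of a line difference at 1 stage was 0.0585 on the log2 scale.

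Mean signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp with an offset of 50) and normalised within arrays by loess with control spots at weight 0. Ratios were turned as log2 of NIL(TGW6) over Nipponbare. A probe was kept if it was well above background in 1 line on both arrays of at least 1 stage, which left 32801 probes after 157 were lost to outlier marks. Of the 29690 loci with a probe, 22710 genes were tested, each by its brightest kept probe, and 6418 had more than 1 kept probe. The array has 0 probes with the locus ID of TGW6 itself, so that gene is not analysed here.

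The line difference at each stage and the difference between the stages were fitted in 1 limma model over the 4 arrays, with a gene-specific dye term and empirical Bayes moderation. The dye term is the same thing as the replicate number and acts as the replicate block. That model left 1 residual degree of freedom and took 9.388 from the prior. The line difference over both stages was tested on the 2 stage means, each the average of a dye-swapped pair, with a prior of 2.924 degrees of freedom. The stages lie on different arrays, so each line's change from 3 to 6 DAH was tested on single-channel levels after Aquantile normalisation between arrays, with a dye term and an intraspot correlation of 0.9082 (limma and statmod 1.5.0; 3 residual degrees of freedom and a prior of 2.825). P-values were adjusted by Benjamini-Hochberg over the genes tested at a threshold of 0.05. Files were read with the packages jsonlite (2.0.0) and data.table (1.17.8). Dye deviations of the 3 DAH and 6 DAH pairs correlated at r = 0.603 across genes, which are not independent replicates.

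The design, the tests and 28 gene lists were fixed before the data were examined. They cover storage proteins, endosperm regulators, starch synthesis, sucrose supply, glycolysis, amino acid transport, grain size, auxin metabolism, auxin response, cytokinin, gibberellin, ethylene, ABA and late embryogenesis, MADS-box genes, cell cycle and replication, histones, ribosomal proteins, proteasome, protein folding in the ER, cell wall, heat shock, defence-related genes, resistance-gene-like genes, transposon-related genes, and markers of embryo, aleurone and oil bodies, green pericarp, and nucellus and maternal tissue. Members were chosen by locus ID from general knowledge or by words in the descriptions. Whether capitals in those words had to match was decided after the descriptions were seen. Some members do not do what the list's name says: the gibberellin list holds a ribosomal protein L9, the ethylene list an auxin efflux carrier, and the defence list transcription factors of the ERF family. Lists were tested with camera against all other genes at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 28 lists. For the line differences that estimate rests on 1 residual degree of freedom, and 0 lists passed in any of these comparisons (limma; 0 at an unadjusted p under 0.05). The test itself then has 1 degree of freedom as well, so hardly any list could pass. For ABA and late embryogenesis genes at 6 DAH the estimate was -0.0151, below the preset value. Their camera p still went from 3.09e-12 to 0.0765. For line differences this test therefore cannot check the preset one. Shares of calls on chromosome 6 were compared with Fisher's exact test, two-sided.

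Genes named in the text follow a rule fixed beforehand. It takes TGW6, then per comparison the 8 largest rises and 8 largest falls among genes past the threshold with the same sign on every array and an informative description, and then up to 3 members of each list. For the share on chromosome 6 it takes up to 5 called genes on either side of TGW6. The words on sign were read as referring to the arrays of the comparison, entries without a match or without a class were counted as uncharacterised, and the genes printed are a subset of those the rule gives, picked after their values were seen. Where a line or stage was not well above background on any array, the fold is a bound: the level of the brighter group over the dimmer group's level, the latter raised to the lowest level that counted as well above background in its channels, per channel.

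The procedure was tested on simulated data whose gene variances were drawn from the prior fitted to these arrays, in 10 draws with 200 changed genes of 22710. At a log2 change of 0.5 it recovered 99.3% at 3 DAH, 99.4% at 6 DAH and 88.8% for the difference between stages, and at log2 changes of 1 and 2 it recovered 100% in each. Over both stages it recovered 0% at 0.5, 0.149% at 1 and 15.9% at 2. For the change from 3 to 6 DAH it recovered 3.28% in Nipponbare and 5.52% in NIL(TGW6) at a log2 change of 1, and 63.6% and 69.1% at 2. Of the calls, 12.6% at 3 DAH, 14.3% at 6 DAH and 15.6% for the difference were false, which is more than the threshold allows. Over both stages 10.9% were false (0% to 100% per draw). For the change from 3 to 6 DAH 0.674% were false in Nipponbare and 0.202% in NIL(TGW6). The arrays themselves had a heavier tail than that prior: at the quantile 0.999 the ratio of residual variance to prior variance was 48.1, against 22.1 under the prior. With 50% of genes changed, 3.19%, 3.53% and 3.36% of the calls at 3 DAH, at 6 DAH and for the difference were false. Of those of at least 2-fold 0 were false, which the setup nearly fixed. Unchanged genes were set to 0 with simulated errors far below 2-fold. Over both stages 31 of 766 calls of at least 2-fold were false. For the stage changes 29 of 16174 were false in Nipponbare and 25 of 9494 in NIL(TGW6). Genes of small change that only just pass are less certain by the false calls above. The 0 does not test how certain genes of at least 2-fold are.

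Alternatives were no background subtraction, the deposited processed signals, the deposited log ratios, Aquantile or quantile normalisation, no filter or a stricter filter on dim probes, no dye term, the mean of a gene's probes, a prior with a trend on intensity, a 2-fold threshold, and each array left out in turn, then without the dye term and, for the stage contrasts, with the intraspot correlation of all 4 arrays. A robust prior, leaving out chromosomes 6 and 7, description words matched without regard to case, a call of 2-fold the same way on all 4 arrays, and other scalings for the gene lists were chosen after seeing the data.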

Results

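Gene expression was measured in developing endosperm of Nipponbare and NIL(TGW6) at 3 and 6 DAH. There were 4 arrays, 2 per stage, each carrying both lines in swapped dyes. The series compares the lines during early grain filling, when the endosperm passes from nuclear division and cell formation to storage. TGW6, the locus of the line's name, encodes an enzyme known to release the auxin IAA from its glucose ester. The array has 0 probes with its locus ID, so its transcript is not analysed here. Per channel, between 72.75% and 76.34% of probe spots were well above background, and 22710 genes were tested. Across genes, which are not independent replicates, the ratios of the 2 arrays of a stage correlated at r = 0.91 at 3 DAH and r = 0.854 at 6 DAH once turned to the same direction. The line differences of the stages correlated at r = 0.285. Values below are log2 ratios of NIL(TGW6) over Nipponbare with the moderated standard error (SE) and n = 2 arrays per stage. Adjusted p for genes is from limma and for lists from camera with the preset correlation, both with Benjamini-Hochberg. For line differences the list test with an estimated correlation has 1 degree of freedom. Hardly any list could pass it, so its adjusted p-values neither back nor weaken the preset test. Counts of list members called over all genes are followed by those adjusted over the list alone where they differ, and are otherwise the same adjusted over the list alone.

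Which genes differed between the lines at 3 DAH was the opening comparison, and storage protein genes were higher in NIL(TGW6). A glutelin gene (Os02g0268100), of the main seed storage protein family of rice, was 15-fold higher (log2 3.91, SE 0.057, n = 2, adjusted p = 2.9e-12). Glutelin type-B 2 (Os02g0249000) was 5.21-fold higher (log2 2.38, SE 0.057) and prolamin 7 (Os05g0328800) 5.02-fold higher (log2 2.33, SE 0.12). Among genes with an informative description the largest fall was in a DRE-binding protein 1A (Os08g0545500), of a family that activates cold and drought genes, which was 63.4-fold lower in NIL(TGW6) (log2 -5.99, SE 0.062, n = 2, adjusted p = 8.6e-13). Glutamate decarboxylase isozyme 3 (Os03g0236200), which makes the amino acid GABA, was 40.1-fold lower (log2 -5.33, SE 0.071). In all, 156 genes were at least 2-fold higher and 900 at least 2-fold lower in NIL(TGW6), all past the adjusted threshold.

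Of 36 storage protein genes measured at 3 DAH, 25 rose and 7 fell, with 18 at least 2-fold up and 0 at least 2-fold down (median 0.972, adjusted p = 8.56e-08). Endosperm regulators went the same way, with 10 of 11 higher and 1 lower (median 0.631, adjusted p = 0.000267). Among them was the transcriptional activator Os07g0182000, a bZIP factor that switches on storage protein genes (log2 1.48, SE 0.06, 2.79-fold). The Dof-type factor Os02g0252400, its partner at the same promoters, rose 2.22-fold (log2 1.15, SE 0.057). Ribosomal proteins, the core of protein synthesis, rose by less but in most members. Of 243, 187 were higher and 8 lower, with 0 at least 2-fold either way (190 and 8 adjusted over the list alone, median 0.281, adjusted p = 4.22e-15). The 40S ribosomal protein S13 (Os07g0572900) rose 1.72-fold (log2 0.779, SE 0.058). Each of these 3 lists had adjusted p = 0.657 with an estimated correlation. Chorismate mutase (Os12g0578200), which leads to phenylalanine and tyrosine, rose 8.65-fold (log2 3.11, SE 0.058). A NAM domain protein (Os02g0214500) rose 4.69-fold (log2 2.23, SE 0.062). A MYB-related protein (Os01g0977300) rose 5.88-fold (log2 2.56, SE 0.069) and was above background on 1 of the 2 arrays in Nipponbare.

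Starch and sucrose genes were divided at 3 DAH. Of 28 starch synthesis genes 9 were higher and 10 lower (10 and 10 adjusted over the list alone, median -0.0455, adjusted p = 0.898). Brittle-1 (Os02g0202400), which carries ADP-glucose into the plastid, was 2.09-fold higher (log2 1.06, SE 0.069). A starch synthase (Os06g0229800) was 1.95-fold higher (log2 0.963, SE 0.063). A large subunit of ADP-glucose pyrophosphorylase (Os05g0580000), which makes that sugar nucleotide, was 1.99-fold lower (log2 -0.989, SE 0.06). Of 16 sucrose supply genes 8 were higher and 4 lower (8 and 5 adjusted over the list alone, median 0.135, adjusted p = 0.168). The sucrose synthase Os03g0340500, which splits incoming sucrose, was 2.12-fold higher (log2 1.08, SE 0.057). The sucrose transporter Os03g0170900 was 2.08-fold higher (log2 1.05, SE 0.057). Orthophosphate dikinase (Os05g0405000) rose 2.2-fold (log2 1.14, SE 0.057).

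Lists that fell in NIL(TGW6) at 3 DAH covered chromatin, hormone response and defence. Of 47 histone genes 35 fell and 5 rose (median -0.358, adjusted p = 5.99e-06), among them a histone H2A (Os03g0279200, log2 -1.3, SE 0.057, 2.46-fold). Of 140 defence-related genes 78 fell and 28 rose (79 and 29 adjusted over the list alone, median -0.238, adjusted p = 0.000843). A class III chitinase (Os11g0701800), of a family that attacks fungal cell walls, was at least 12-fold lower. Of 24 MADS-box genes 15 fell and 2 rose (16 and 2 adjusted over the list alone, median -0.287, adjusted p = 0.00533), among them the floral organ gene SPW1 (Os06g0712700, log2 -1.17, SE 0.057, 2.25-fold). SPW1 lies on chromosome 6, where probes may pair poorly with the allele of the NIL. The call of the MADS-box list was lost without replicate 1 of 3 DAH (adjusted p = 0.128) and without replicate 2 of 3 DAH (adjusted p = 0.314). Auxin response genes fell in 42 of 78 and rose in 11 (median -0.183, adjusted p = 0.00902). The AUX/IAA gene Os02g0805100, of a family of auxin response repressors, was 13.1-fold lower (log2 -3.71, SE 0.06). The SAUR gene Os04g0662400 was 6.47-fold lower (log2 -2.69, SE 0.058). Ethylene genes fell in 26 of 53 and rose in 13 (median -0.136, adjusted p = 0.0138). Ethylene responsive element binding factor 4 (Os05g0497200) was 8.38-fold lower (log2 -3.07, SE 0.069). With an estimated correlation each of these 5 lists had adjusted p = 0.657.

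Among further large falls at 3 DAH, another DRE-binding protein 1A (Os09g0522200) was 31.1-fold lower (log2 -4.96, SE 0.085) and the AP2 factor RAP2.6 (Os08g0474000) 34.4-fold lower (log2 -5.1, SE 0.062). A Zn-finger factor (Os05g0525900) was 37-fold lower (log2 -5.21, SE 0.072). WRKY transcription factor 28 (Os06g0649000) was 29.8-fold lower (log2 -4.9, SE 0.059) and above background on 1 of the 2 arrays in NIL(TGW6). Cinnamate 4-hydroxylase (Os02g0467600), an early enzyme of the lignin and flavonoid pathway, was 34.5-fold lower (log2 -5.11, SE 0.067). An expansin (Os10g0542400), which loosens cell walls, was 12.6-fold lower (log2 -3.65, SE 0.06). A DnaJ heat shock protein (Os08g0548400) was 10.6-fold lower (log2 -3.4, SE 0.062) and a small heat shock protein (Os03g0266900) 5.9-fold lower (log2 -2.56, SE 0.057). In auxin metabolism 3 of 6 genes rose and 2 fell (3 and 3 adjusted over the list alone, median 0.156, adjusted p = 0.769). The alliinase domain gene Os05g0169300, of the family that starts IAA synthesis from tryptophan, rose 2.9-fold (log2 1.54, SE 0.057). The GH3 homolog Os07g0592600, of a family that conjugates IAA to amino acids, fell 2.01-fold (log2 -1.01, SE 0.06).

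Markers of other grain tissues did not pass as lists at 3 DAH. The sample titles name endosperm, yet the brightest green pericarp marker (Os01g0600900, chlorophyll a-b binding) had log2 levels of 16.4 to 16.9 across lines and stages. Outer tissue in the samples of both lines is therefore possible. Of 62 green pericarp markers 27 were lower and 13 higher (median -0.0913, adjusted p = 0.316). Of 32 nucellus and maternal markers 14 were lower and 8 higher (median -0.137, adjusted p = 0.168). Of 44 aleurone and oil markers 18 were lower and 13 higher (median -0.0499, adjusted p = 0.769), and both of the 2 embryo markers were lower (median -0.57, adjusted p = 0.168). Of the maternal list, a chalcone synthase family gene (Os02g0205500) was 6.82-fold lower (log2 -2.77, SE 0.058) and chalcone synthase Os07g0526400 5.27-fold lower (log2 -2.4, SE 0.058), while another chalcone synthase (Os07g0271500) was above background in neither line.

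The remaining lists did not pass at 3 DAH either. Medians were 0.0989 for amino acid transport, 0.042 for the proteasome, -0.0996 for transposon-related genes and -0.0652 for heat shock genes, each with adjusted p = 0.168. Transposon-related genes passed with the deposited processed signals (adjusted p = 0.0482) and heat shock genes without replicate 2 of 3 DAH (adjusted p = 0.0272). Protein folding in the ER had a median of -0.158 (adjusted p = 0.269), grain size genes 0.0752 and gibberellin genes -0.0829 (each adjusted p = 0.452), and resistance-gene-like genes -0.0383 (adjusted p = 0.582). Cell wall genes had a median of -0.067 (adjusted p = 0.71), cell cycle and replication -0.00119 (adjusted p = 0.769), and glycolysis 0.00537 (adjusted p = 0.79). ABA and late embryogenesis genes (median -0.0306) and cytokinin genes (median -0.00975) each had adjusted p = 0.898. In 5 of the 20 lists not past the test the median, mean and test differed in sign, namely ABA and late embryogenesis, cell cycle, cytokinin, glycolysis and starch synthesis.

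For NIL(TGW6) vs Nipponbare at 3 DAH, 6554 genes were higher and 7648 lower at the adjusted threshold, 62.5% of those tested, and most of these changes were under 2-fold. Of the called genes 46.1% were higher here and 57.2% with the deposited processed signals. Among genes at least 2-fold apart 14.8% were higher here, against 27.8% of 1810 with those signals. The number called was 8154 without replicate 1 and 5822 without replicate 2 of 3 DAH, and 8700 without the replicate block.

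**Figure D1:**
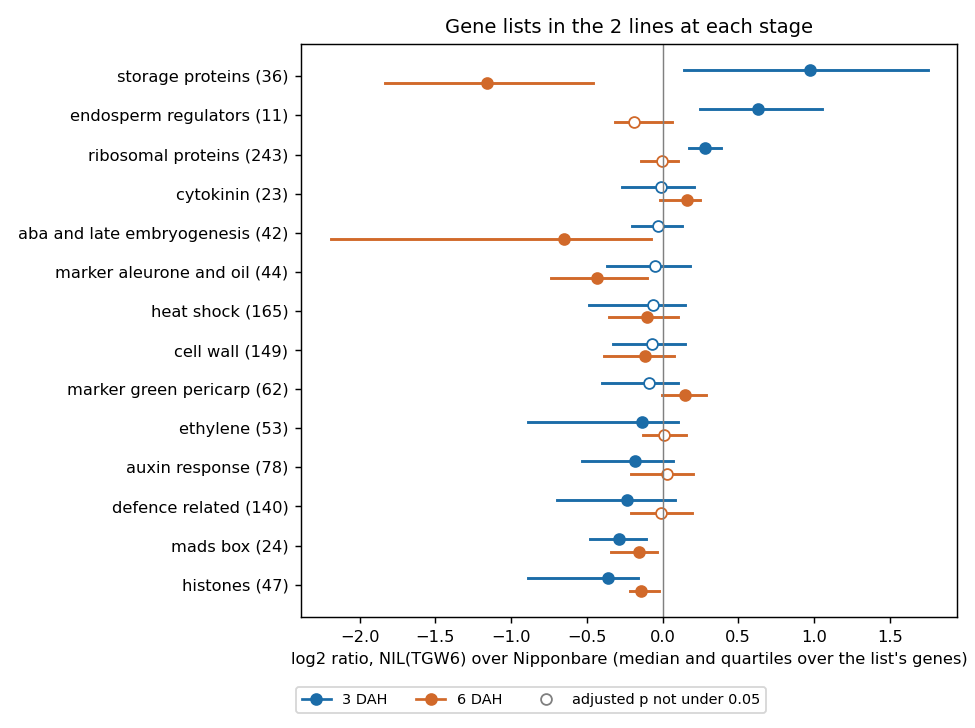
Median (points) and quartiles (lines) of the log2 ratio of NIL(TGW6) over Nipponbare for the 14 lists past the test with preset correlation at either stage, with the number of genes in brackets and open points where adjusted p was not under 0.05. Storage proteins had a median of 0.972 at 3 DAH and -1.16 at 6 DAH.

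The same comparison of the lines at 6 DAH gave lower storage protein genes in NIL(TGW6). Of the 36 measured, 31 fell and 0 rose, 22 of them at least 2-fold (32 and 0 adjusted over the list alone, median -1.16, adjusted p = 7.62e-19, and adjusted p = 0.872 with an estimated correlation). A 13 kDa prolamin (Os07g0206400) was 8.17-fold lower (log2 -3.03, SE 0.058, n = 2, adjusted p = 6.4e-11) and another (Os07g0206500) 5.76-fold lower (log2 -2.53, SE 0.082). Embryonic abundant protein 1 (Os01g0159600) was at least 33.1-fold lower (n = 2, adjusted p = 1.6e-12). Dehydrin RAB25 (Os01g0702500) was 24-fold lower (log2 -4.59, SE 0.092) and dehydrin RAB 16B (Os11g0454200) 19.9-fold lower (log2 -4.31, SE 0.068), both of a family that protects cells as they lose water. In all, 73 genes were at least 2-fold higher and 394 at least 2-fold lower in NIL(TGW6).

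ABA and late embryogenesis genes fell in 28 of 42 and rose in 4, with 18 at least 2-fold lower (29 and 4 adjusted over the list alone, median -0.652, adjusted p = 4.33e-11). The ABA-induced membrane protein PM 19 (Os05g0381400) was 11.9-fold lower (log2 -3.57, SE 0.064). Aleurone and oil markers fell in 30 of 44 and rose in 6 (median -0.431, adjusted p = 2.67e-07). Alpha-amylase 3E (Os08g0473600), which breaks down starch, was 4.46-fold lower (log2 -2.16, SE 0.059). An oleosin (Os09g0324000), a coat protein of oil bodies, was 2.44-fold lower (log2 -1.29, SE 0.059). Cell wall genes fell in 68 of 149 and rose in 26 (69 and 26 adjusted over the list alone, median -0.113, adjusted p = 0.00369). A xyloglucan endo-transglycosylase (Os06g0696500), which remodels wall polymers, was 3.38-fold lower (log2 -1.76, SE 0.057). Heat shock genes fell in 66 of 165 and rose in 27 (67 and 28 adjusted over the list alone, median -0.0999, adjusted p = 0.00369). Heat shock protein 70 (Os03g0277300) was 4.33-fold lower (log2 -2.11, SE 0.058). Each of these 4 lists had adjusted p = 0.872 with an estimated correlation.

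Histones fell at 6 DAH in 20 of 47 and rose in 2, with 0 at least 2-fold apart (median -0.141, adjusted p = 0.0157). A histone H2A (Os03g0721900) was 1.45-fold lower (log2 -0.541, SE 0.058). MADS-box genes fell in 12 of 24 and rose in 2 (14 and 2 adjusted over the list alone, median -0.157, adjusted p = 0.0232). SPW1 (Os06g0712700) was again among them (log2 -1.22, SE 0.057, 2.33-fold). Cytokinin genes rose in 13 of 23 and fell in 1 (13 and 2 adjusted over the list alone, median 0.161, adjusted p = 0.0302). A response regulator receiver protein (Os08g0458600), of a family that relays the cytokinin signal, was 3.53-fold higher (log2 1.82, SE 0.057). The response regulator ARR1 (Os02g0182100) was 1.49-fold higher (log2 0.573, SE 0.058). Green pericarp markers rose in 24 of 62 and fell in 9 (26 and 9 adjusted over the list alone, median 0.146, adjusted p = 0.0302). The photosystem II gene Os07g0147500 was 1.62-fold higher (log2 0.698, SE 0.077). With an estimated correlation the green pericarp list had adjusted p = 0.883 and the other 3 had adjusted p = 0.872.

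These 4 calls at 6 DAH were also lost when arrays were left out, in fits that then go without the dye term. Leaving out an array of 3 DAH does not alter the 6 DAH ratio of a gene, and the histones kept their median of -0.141. Losses without a 3 DAH array therefore come from the changed fit. For MADS-box genes and green pericarp markers this held for each of the 4 arrays (adjusted p from 0.0585 to 0.162 and from 0.0826 to 0.162). For histones it held without replicate 1 of 3 DAH (adjusted p = 0.38), replicate 2 of 3 DAH (adjusted p = 0.399) or replicate 1 of 6 DAH (adjusted p = 0.54), and for cytokinin without replicate 1 of 6 DAH (adjusted p = 0.0826). With the deposited processed signals cytokinin (adjusted p = 0.0664) and green pericarp (adjusted p = 0.107) did not pass.

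Of other genes at 6 DAH, a Glossy1 homolog (Os06g0653000), of the family that makes cuticular wax, was 5.62-fold higher in NIL(TGW6) (log2 2.49, SE 0.064). A homeodomain leucine zipper gene (Os07g0581700) was 4.86-fold higher (log2 2.28, SE 0.058) and an anionic peroxidase (Os04g0688100) 4.08-fold higher (log2 2.03, SE 0.059). ACC oxidase 1 (Os02g0771600), which makes ethylene, was 2.38-fold higher (log2 1.25, SE 0.057). Other falls were in an acidic beta-1,3-glucanase (Os01g0942300, log2 -4.05, SE 0.073, 16.6-fold) and gibberellin-regulated protein 2 (Os05g0432200, log2 -4.02, SE 0.057, 16.2-fold). A Bowman-Birk proteinase inhibitor (Os01g0127600) fell 8.24-fold (log2 -3.04, SE 0.064).

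Of 28 starch synthesis genes 7 were higher and 8 lower at 6 DAH (median 0.0642, adjusted p = 0.871). Starch-branching enzyme I (Os06g0726400) was 1.39-fold lower (log2 -0.472, SE 0.058). Sucrose supply genes were lower in 9 of 16 and higher in 2 (median -0.192, adjusted p = 0.174). The sucrose synthase Os03g0340500 was 1.45-fold lower (log2 -0.534, SE 0.057) and the sugar transporter gene NEC1 (Os02g0513100) 1.58-fold lower (log2 -0.664, SE 0.059). Without replicate 1 of 6 DAH the branching enzyme (adjusted p = 0.082), the sucrose synthase (adjusted p = 0.22), the histone Os03g0721900 (adjusted p = 0.18) and ARR1 (Os02g0182100, adjusted p = 0.064) no longer passed.

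The other lists did not pass at 6 DAH. Cell cycle and replication genes had a median of 0.0486 (adjusted p = 0.0645) and passed with the deposited processed signals (adjusted p = 0.038). Medians were 0.0402 for amino acid transport (adjusted p = 0.174), -0.189 for endosperm regulators (adjusted p = 0.212), 0.0629 for resistance-gene-like genes (adjusted p = 0.28) and -0.0328 for glycolysis (adjusted p = 0.346). Auxin metabolism (median -0.0806) and nucellus and maternal markers (median -0.109) each had adjusted p = 0.433. The proteasome had a median of 0.00482 (adjusted p = 0.597), grain size genes -0.0692 (adjusted p = 0.616) and ethylene genes 0.0114 (adjusted p = 0.871). Adjusted p was 0.912 for ribosomal proteins (median -0.0019), auxin response (0.0314), defence-related genes (-0.0111), gibberellin (-0.0417), protein folding in the ER (0.0154), transposon-related genes (-0.0198) and embryo markers (-0.0509). The median, mean and test differed in sign in 3 lists not past the test, namely auxin response, ethylene and protein folding.

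For NIL(TGW6) vs Nipponbare at 6 DAH, 5295 genes were higher and 5719 lower at the adjusted threshold, 48.5% of those tested. Among genes at least 2-fold apart 15.6% were higher, against 30.3% of 955 with the deposited processed signals. The number called was 2681 without replicate 1 of 6 DAH, with 37.4% of them higher against 48.1% on all arrays. It was 2283 without replicate 2 of 6 DAH and 4519 without the replicate block.

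**Figure D2:**
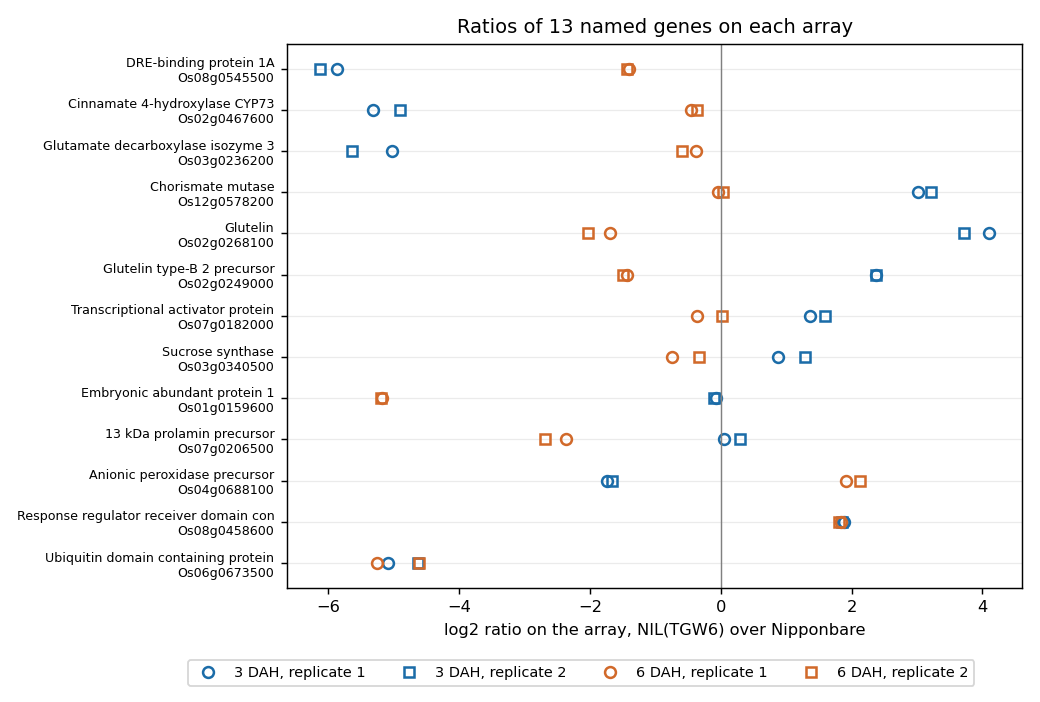
Log2 ratio of NIL(TGW6) over Nipponbare on each of the 4 arrays for 13 named genes, 2 arrays per stage. The glutelin Os02g0268100 lay above 0 on both arrays at 3 DAH and below 0 on both at 6 DAH, Os01g0159600 was above background in neither line at 3 DAH nor in NIL(TGW6) at 6 DAH, and Os06g0673500 was not above background in NIL(TGW6).

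Whether the line difference itself changed between the stages was tested directly, as that at 6 DAH minus that at 3 DAH. Storage proteins turned from higher to lower in NIL(TGW6), with 29 of 36 genes past this test downwards and 2 upwards (29 and 3 adjusted over the list alone, median -2.67, adjusted p = 1.22e-18). The glutelin Os02g0268100 moved by -5.77 (SE 0.081, n = 2 arrays per stage, adjusted p = 5.8e-11). Ribosomal proteins moved down in 149 of 243 and up in 11 (156 and 13 adjusted over the list alone, median -0.302, adjusted p = 3.98e-12). ABA and late embryogenesis genes moved down in 25 of 42 and up in 5 (26 and 5 adjusted over the list alone, median -0.904, adjusted p = 5.33e-09), dehydrin 9 (Os11g0451700) by -3.6 (SE 0.081). Endosperm regulators moved down in 8 of 11 and up in 0 (median -0.846, adjusted p = 2.41e-05), the activator Os07g0182000 by -1.65 (SE 0.084). Sucrose supply genes moved down in 9 of 16 and up in 2 (10 and 2 adjusted over the list alone, median -0.307, adjusted p = 0.0093), the sucrose synthase Os03g0340500 by -1.62 (SE 0.081). With an estimated correlation each of these 5 lists had adjusted p = 0.67, and sucrose supply had adjusted p = 0.0504 with the series matrix values.

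Lists that moved upwards in this test included most of those lower in NIL(TGW6) at 3 DAH. Histones moved up in 24 of 47 and down in 5 (median 0.285, adjusted p = 0.00149), and defence-related genes up in 63 of 140 and down in 29 (65 and 32 adjusted over the list alone, median 0.148, adjusted p = 0.0093). Both had adjusted p = 0.708 with an estimated correlation. Ethylene genes moved up in 25 of 53 and down in 13 (27 and 14 adjusted over the list alone, median 0.208, adjusted p = 0.0093), and auxin response genes up in 37 of 78 and down in 10 (38 and 12 adjusted over the list alone, median 0.194, adjusted p = 0.0127). Both had adjusted p = 0.67 with an estimated correlation. Green pericarp markers moved up in 31 of 62 and down in 5 (median 0.214, adjusted p = 0.0127, and adjusted p = 0.452 without replicate 2 of 3 DAH). Aleurone and oil markers moved down in 21 of 44 and up in 12 (21 and 13 adjusted over the list alone, median -0.176, adjusted p = 0.0161, and adjusted p = 0.127 with the deposited processed signals). Both marker lists had adjusted p = 0.723 with an estimated correlation. A phosphate-induced family protein (Os02g0756600) moved by 5.07 (SE 0.083), a class III chitinase (Os11g0702100) by 4.12 (SE 0.082), and ethylene responsive element binding factor 4 (Os05g0497200) by 3.56 (SE 0.097). The oleosin Os09g0324000 moved by -2.05 (SE 0.083).

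Some lists called at only 1 stage did not pass the test of the difference. Those called at 6 DAH alone were cell wall (median of the difference -0.128, adjusted p = 0.0823), cytokinin (0.23, adjusted p = 0.209) and heat shock (-0.0246, adjusted p = 0.613). Across all genes the difference passed in 6093 upwards and 5307 downwards, 876 and 411 of them at least 2-fold. With the deposited processed signals 1320 and 846 were at least 2-fold, and with the series matrix values 1277 and 791. The total of 11400 was 5435 without the replicate block and between 3958 and 5956 when single arrays were left out. In 5 of 17 lists not past this test the median, mean and test differed in sign.

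Over both stages together 8 genes were lower in NIL(TGW6) and 0 were higher (limma on 2 stage means, 1765 genes at an unadjusted p under 0.05), and all 8 lie on chromosomes 6 and 7. Probes designed on Nipponbare may pair poorly with the allele of the NIL there. The values below cannot tell that from lower transcript levels. The ubiquitin domain gene Os06g0673500, of a family that tags proteins for degradation, was at least 25-fold lower at 3 DAH and at least 26.6-fold lower at 6 DAH (adjusted p = 0.022, n = 2 stage means). An uncharacterised transcript (Os06g0722400), above background in both lines, had -6.71 (SE 0.17, adjusted p = 0.022). Of the others on chromosome 6, Os06g0614400 had -5 (SE 0.13), Os06g0616400 -4.75 (SE 0.13) and the non-coding transcript Os06g0690600 -3.89 (SE 0.14, adjusted p = 0.035). On chromosome 7, Os07g0255300 had -5.14 (SE 0.15), Os07g0297400 -4.74 (SE 0.14) and Os07g0294300 -4.17 (SE 0.14, adjusted p = 0.029). Os06g0616400 was at least 23.8-fold lower at 3 DAH and at least 21.6-fold lower at 6 DAH. Os07g0255300 was at least 28.2-fold lower at 6 DAH, and NIL(TGW6) was above background on 1 of the 2 arrays at 3 DAH. The TAT-binding protein homolog Os06g0600100, of the proteasome's regulatory family, was at least 10.5-fold lower at 3 DAH and at least 18.8-fold lower at 6 DAH, and did not pass over both stages (adjusted p = 0.067). The coactivator Os06g0592500 was 15.3-fold lower at 3 DAH and 4.01-fold lower at 6 DAH (log2 -3.93 and -2, SE 0.068).

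None of the 8 genes was called over both stages with the deposited processed signals (1787 genes at an unadjusted p under 0.05, limma), the series matrix values (1835 genes) or without the filter on dim probes (2337 genes). Their log2 ratios ran from -4.05 to -7.88 with the processed signals (adjusted p from 0.075 to 0.086, limma). Without the filter they ran from -3.89 to -6.71 (adjusted p from 0.056 to 0.076). Without replicate 2 of 3 DAH 3 genes were called. In the fit of all 4 arrays with the replicate block 95 genes were called, 19 higher and 76 lower. The response regulator Os08g0458600 had 1.85 over both stages (SE 0.13, adjusted p = 0.16) and a small heat shock protein (Os01g0136200) -1.46 (SE 0.13, adjusted p = 0.22). Neither passed on stage means, and both did with the replicate block (adjusted p = 0.013 and 0.022).

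A total of 7 lists passed over both stages although 0 of their members passed singly over all genes. They were ribosomal proteins (median 0.13, adjusted p = 3.24e-07), histones (-0.261, adjusted p = 9.34e-06), MADS-box genes (-0.201, adjusted p = 0.000541) and aleurone and oil markers (-0.245, adjusted p = 0.000541). The others were ABA and late embryogenesis (-0.311, adjusted p = 0.0017), heat shock (-0.067, adjusted p = 0.0122) and defence-related genes (-0.141, adjusted p = 0.0308). Each had adjusted p = 0.822 with an estimated correlation. Adjusted over the list alone, 1 MADS-box gene and 9 heat shock genes were lower. Cell wall genes (median -0.0989, adjusted p = 0.0516) and auxin response genes (-0.121, adjusted p = 0.1) passed with the deposited processed signals (adjusted p = 0.0441 and 0.029), and the proteasome (0.0278, adjusted p = 0.17) without replicate 1 of 6 DAH (adjusted p = 0.0472). Cell wall genes passed as well without background subtraction (adjusted p = 0.0438) and without replicate 2 of 3 DAH (adjusted p = 0.0383). In 3 of the 21 lists not past the test the median, mean and test differed in sign. Of the 7 lists past over both stages, only histones and MADS-box genes also passed at each stage. Ribosomal proteins and defence-related genes did not pass at 6 DAH (medians -0.0019 and -0.0111). ABA and late embryogenesis, aleurone and oil, and heat shock did not at 3 DAH (medians -0.0306, -0.0499 and -0.0652).

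The share of changed genes on chromosome 6, which carries the introgressed locus, was compared with that on the other chromosomes. Genes at least 2-fold the same way on all 4 arrays numbered 120, of which 107 were lower and 13 higher in NIL(TGW6), and 54.2% of them lay on chromosomes 6 and 7. On chromosome 6, 39 of 1780 tested genes were of this kind (2.19%), with 81 on all others (odds ratio 5.76, 95% interval 3.82 to 8.58, Fisher's exact p = 5.28e-15). This test was chosen after the data were seen. Chromosome 7 had 26 of 1798 (1.45%), and no other chromosome exceeded 0.407%. Genes of chromosome 6 were also called more often at 3 DAH (65.4% against 62.3%, odds ratio 1.15, exact p = 0.0086) and at 6 DAH (54.9% against 48%, odds ratio 1.32, exact p = 1.49e-08). Over both stages it held 5 of the 8 called genes (odds ratio 19.6, exact p = 0.000135). With the deposited processed signals, the series matrix values or no filter on dim probes 0 genes were called over both stages, so no share exists there. With a 2-fold minimum the odds ratio was 1.42 at 3 DAH (exact p = 0.000997) and 2.86 at 6 DAH (exact p = 3.64e-15).

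Of the called genes nearest to TGW6 in locus order, up to 5 per side at each stage, some were higher and some lower in NIL(TGW6). Cinnamoyl-CoA reductase (Os06g0623600), the enzyme that commits precursors to lignin, was 1.41-fold lower at 3 DAH (log2 -0.498, SE 0.058) and 1.14-fold lower at 6 DAH (log2 -0.185, SE 0.058). The call at 6 DAH was lost with the deposited processed signals (adjusted p = 0.068), without the replicate block (adjusted p = 0.17) and with any single array left out, which also drops that block. Without an array of 3 DAH its log2 ratio at 6 DAH stayed at -0.185. On the other side the uncharacterised gene Os06g0624700 was 1.58-fold higher at 3 DAH (log2 0.658, SE 0.059) and 1.71-fold higher at 6 DAH (log2 0.771, SE 0.059). A glycosyl transferase (Os06g0625700) was 1.76-fold higher at 3 DAH (log2 0.818, SE 0.058) and 1.12-fold higher at 6 DAH (log2 0.157, SE 0.058). The other genes printed here were uncharacterised, and some called genes with a description, such as the bZIP gene Os06g0622700, are not printed. Os06g0623300 was 1.34-fold lower at 3 DAH (log2 -0.418, SE 0.059) and 1.79-fold lower at 6 DAH (log2 -0.836, SE 0.059). Os06g0622400 was 2.51-fold higher at 3 DAH (log2 1.33, SE 0.057) and at least 1.22-fold higher at 6 DAH. Os06g0626200 was 2.59-fold lower at 3 DAH (log2 -1.37, SE 0.082) and 1.55-fold lower at 6 DAH (log2 -0.637, SE 0.082).

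**Figure D3:**
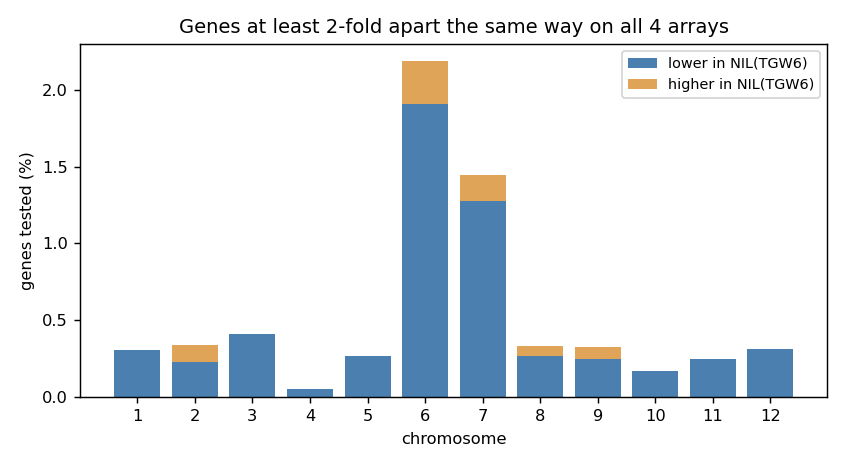
Percent of tested genes per chromosome that were at least 2-fold lower or higher in NIL(TGW6) on all 4 arrays. Chromosome 6 reached 2.19% and chromosome 7 reached 1.45%, and the others lay between 0.0505% and 0.407%.

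How expression changed from 3 to 6 DAH was compared within each line, and storage protein genes rose steeply in both. In Nipponbare globulin 1 (Os03g0663800), a seed storage protein, rose 443-fold (log2 8.79, SE 0.29, n = 2, adjusted p = 1.5e-05) and was above background on 1 of the 2 arrays at 3 DAH. A prolamin (Os07g0219300) rose at least 287-fold and glutelin II (Os10g0400200) 191-fold (log2 7.58, SE 0.12). In NIL(TGW6) the prolamin rose at least 70.4-fold, globulin 1 52.9-fold (log2 5.73, SE 0.29) and glutelin II 29-fold (log2 4.86, SE 0.12). Of the 36 storage protein genes 31 rose and 3 fell in Nipponbare (median 5.69, adjusted p = 1.13e-118). In NIL(TGW6) 32 rose and 1 fell (32 and 2 adjusted over the list alone, median 3.52, adjusted p = 1.47e-61). These changes compare different arrays, and the lines share arrays, so the changes of the lines are not independent of each other.

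Endosperm regulators rose in 10 of 11 in Nipponbare (median 2.28, adjusted p = 3.94e-13) and in 8 of 11 in NIL(TGW6) (10 adjusted over the list alone, median 0.791, adjusted p = 2.16e-08), with 0 falling in either line. The activator Os07g0182000 rose 18.6-fold in Nipponbare (log2 4.22, SE 0.11) and 5.92-fold in NIL(TGW6) (log2 2.56, SE 0.11). The NF-Y subunit Os02g0725900, of a family of endosperm transcription factors, rose 16.2-fold and 11.2-fold (log2 4.02 and 3.48, SE 0.17). ABA and late embryogenesis genes rose in 29 of 42 and fell in 1 in Nipponbare (median 1.59, adjusted p = 1.32e-31), and rose in 29 and fell in 3 in NIL(TGW6) (median 0.995, adjusted p = 5.78e-14). Dehydrin RAB25 (Os01g0702500) rose 128-fold in Nipponbare (log2 7, SE 0.34). Aleurone and oil markers rose in 22 of 44 and fell in 12 in Nipponbare (median 0.734, adjusted p = 1.59e-10), and rose in 21 and fell in 11 in NIL(TGW6) (22 and 11 adjusted over the list alone, median 0.367, adjusted p = 1.66e-08). Alpha-amylase 3E (Os08g0473600) rose 123-fold in Nipponbare (log2 6.94, SE 0.1), where 1 of the 2 arrays at 3 DAH was above background. It rose 22.6-fold in NIL(TGW6) (log2 4.5, SE 0.1). The oleosin Os09g0324000 rose 69.5-fold in Nipponbare (log2 6.12, SE 0.13). With an estimated correlation the storage, regulator, ABA and aleurone lists passed in both lines.

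Starch synthesis genes rose in 14 of 28 and fell in 8 in Nipponbare (median 0.24, adjusted p = 0.0173, and adjusted p = 0.143 with an estimated correlation). In NIL(TGW6) 14 rose and 7 fell (median 0.312, adjusted p = 0.00113, and adjusted p = 0.0622 with an estimated correlation). Starch-branching enzyme I (Os06g0726400) rose 10-fold in Nipponbare (log2 3.32, SE 0.09) and 7.44-fold in NIL(TGW6) (log2 2.9, SE 0.09). Isoamylase (Os08g0520900), which trims branches from the growing starch, rose 6.27-fold and 5.79-fold (log2 2.65 and 2.53, SE 0.076). The debranching enzyme Os04g0164900 rose 14.1-fold and 10.4-fold (log2 3.81 and 3.37, SE 0.15) and was above background on 1 of the 2 arrays per line at 3 DAH. ACC oxidase 1 (Os09g0451000) rose 81.3-fold and 50.3-fold (log2 6.35 and 5.65, SE 0.13). The sucrose synthase Os03g0340500 rose 8.47-fold and 2.76-fold (log2 3.08 and 1.46, SE 0.089), while the sucrose transporter Os02g0576600 fell 6.41-fold and 7.54-fold (log2 -2.68 and -2.91, SE 0.17).

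Auxin metabolism genes rose in 4 of 6 and fell in 1 in Nipponbare (5 and 1 adjusted over the list alone, median 2.01, adjusted p = 4.12e-06). In NIL(TGW6) 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.64, adjusted p = 4.4e-07), and both calls held with an estimated correlation. The alliinase domain gene Os05g0169300 rose 7.94-fold in Nipponbare (log2 2.99, SE 0.081). The flavin monooxygenase Os01g0273800, of the family that completes IAA synthesis, rose 5.97-fold in Nipponbare and 4.16-fold in NIL(TGW6) (log2 2.58 and 2.06, SE 0.076). Heat shock genes rose in 63 of 165 and fell in 28 in Nipponbare (median 0.158, adjusted p = 0.0173), and rose in 65 and fell in 22 in NIL(TGW6) (67 and 24 adjusted over the list alone, median 0.227, adjusted p = 0.000207). A class I small heat shock protein (Os01g0136100) rose 20.9-fold and 12.8-fold (log2 4.38 and 3.68, SE 0.16). Ribosomal proteins rose in Nipponbare in 94 of 243 and fell in 17 (90 and 16 adjusted over the list alone, median 0.256, adjusted p = 0.0236). The 60S acidic ribosomal protein P0 (Os11g0135400) rose 2.2-fold there (log2 1.14, SE 0.12).

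Histones fell in 33 of 47 and rose in 4 in Nipponbare (35 and 5 adjusted over the list alone, median -0.819, adjusted p = 0.000339, and adjusted p = 0.117 with an estimated correlation). In NIL(TGW6) 23 fell and 2 rose (25 and 3 adjusted over the list alone, median -0.372, adjusted p = 0.00637, and adjusted p = 0.34 with an estimated correlation), a call also lost with loess within arrays alone (adjusted p = 0.164). Histone H2B.2 (Os05g0574300) fell 3.72-fold in Nipponbare (log2 -1.89, SE 0.16). MADS-box genes fell in 13 of 24 and rose in 4 in Nipponbare (median -0.519, adjusted p = 0.024, and adjusted p = 0.082 with an estimated correlation), a call also lost with the deposited processed signals (adjusted p = 0.0658). In NIL(TGW6) 12 fell and 3 rose (14 and 3 adjusted over the list alone, median -0.541, adjusted p = 0.00623). The PISTILLATA-like gene Os05g0423400, of the floral organ class, fell 3.02-fold and 2.49-fold (log2 -1.59 and -1.32, SE 0.073).

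In Nipponbare the nucellus and maternal markers fell in 14 of 32 and rose in 7 (median -0.267, adjusted p = 0.038). In NIL(TGW6) as many fell and rose (8 rising adjusted over the list alone), and the list did not pass (median -0.215, adjusted p = 0.292). The call in Nipponbare was lost without replicate 1 of 3 DAH (adjusted p = 0.0725), replicate 2 of 3 DAH (adjusted p = 0.0655) or replicate 1 of 6 DAH (adjusted p = 0.0538), and with the deposited processed signals (adjusted p = 0.0658). Chalcone synthase Os07g0526400 fell 34.2-fold in Nipponbare (log2 -5.09, SE 0.1), and 3.79-fold in NIL(TGW6) (log2 -1.92, SE 0.1). In NIL(TGW6) cell wall genes fell in 59 of 149 and rose in 20 (62 and 21 adjusted over the list alone, median -0.2, adjusted p = 0.0034). The extensin domain gene Os05g0531200 rose 12.3-fold (log2 3.62, SE 0.13). Both embryo markers rose there (median 1.82, adjusted p = 0.00738), Homeobox 20 (Os03g0727000) by 4.07-fold (log2 2.03, SE 0.14), against 2.14-fold in Nipponbare (log2 1.1, SE 0.14). Ethylene genes rose in NIL(TGW6) in 21 of 53 and fell in 10 (21 and 11 adjusted over the list alone, median 0.0452, adjusted p = 0.0449, and adjusted p = 0.631 with an estimated correlation). That call was also lost without replicate 2 of 3 DAH (adjusted p = 0.064) or replicate 1 of 6 DAH (adjusted p = 0.0555).

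Among other steep falls from 3 to 6 DAH, the fasciclin domain gene Os02g0726000, of a family of cell surface proteins, fell 37.2-fold in Nipponbare and 10.3-fold in NIL(TGW6) (log2 -5.22 and -3.37, SE 0.082). Lipoxygenase L-2 (Os03g0738600), which oxidises fatty acids, fell at least 29.6-fold and at least 7.63-fold. WRKY transcription factor 28 (Os06g0649000) fell 29.8-fold in Nipponbare (log2 -4.9, SE 0.1) and an RNase S-like gene (Os09g0538000) 36-fold in NIL(TGW6) (log2 -5.17, SE 0.13).

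Over all genes 5784 rose and 6876 fell from 3 to 6 DAH in Nipponbare, 1485 and 1869 of them at least 2-fold. In NIL(TGW6) 5199 rose and 5162 fell, 1180 and 863 of them at least 2-fold. The lists past the test were 11 in Nipponbare and 12 in NIL(TGW6), and 10 and 9 with an estimated correlation. Auxin response (median -0.332, adjusted p = 0.0234) and defence-related genes (median -0.338, adjusted p = 0.00597) passed in Nipponbare with the estimate alone. Their estimates were 0.00281 and 0, below the preset 0.01, which makes the test milder. Of the lists past in only 1 line, the difference between the lines did not pass for nucellus and maternal markers (median -0.0333, adjusted p = 0.613), cell wall genes (-0.128, adjusted p = 0.0823) and embryo markers (0.519, adjusted p = 0.278). In Nipponbare sucrose supply passed with loess within arrays alone (adjusted p = 0.0276) and embryo markers without replicate 1 of 6 DAH (adjusted p = 0.0246). The median, mean and test differed in sign in 0 of 17 lists not past the test in Nipponbare and in 4 of 16 in NIL(TGW6). Genes called with loess within arrays alone numbered 8024 in Nipponbare and 5129 in NIL(TGW6). With the deposited processed signals 5165 and 3604 genes were at least 2-fold apart.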

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

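The tests of outer tissue for both patterns weighed here, the rank correlations and the correlation with the stage change of NIL(TGW6) were chosen after those results were seen, and the others before, but what the age tests require was made stricter and the probe spots below were divided by class after values were seen. The brightest marker genes given below were also picked after their values were seen. The line difference was tested for a change between 3 and 6 DAH, and 11400 genes passed, 1287 of them at least 2-fold, as did 11 lists with the preset correlation. With an estimated correlation 0 lists passed, in a test that hardly any list could pass. Medians of the difference were -2.67 for storage proteins, -0.904 for ABA and late embryogenesis, -0.846 for endosperm regulators, -0.307 for sucrose supply, -0.302 for ribosomal proteins and -0.176 for aleurone and oil markers. They were 0.285 for histones, 0.214 for green pericarp markers, 0.208 for ethylene, 0.194 for auxin response and 0.148 for defence-related genes. Among named genes the difference was -5.77 for the glutelin Os02g0268100, -3.6 for dehydrin 9 (Os11g0451700), -2.05 for the oleosin Os09g0324000, -1.65 for the activator Os07g0182000 and -1.62 for the sucrose synthase Os03g0340500. It was 5.07 for the phosphate-induced protein Os02g0756600, 4.12 for the chitinase Os11g0702100 and 3.56 for the ethylene responsive element binding factor 4 (Os05g0497200). Embryonic abundant protein 1 (Os01g0159600) passed with a fitted value of -5.09, but its size is not determined, since only Nipponbare at 6 DAH was above background, where the line difference is given as at least 33.1-fold.

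Storage protein genes were higher in NIL(TGW6) at 3 DAH and lower at 6 DAH. Grains of different developmental age at the same day could produce this, but NIL(TGW6) would have to be older at 3 DAH and younger at 6 DAH. Across 19105 genes outside the storage list and chromosomes 6 and 7, the line difference at 3 DAH correlated with the mean stage change of the lines at r = 0.255 (rank correlation 0.334). Both measures hold the 3 DAH levels of both lines, and shared errors in Nipponbare raise r while those in NIL(TGW6) lower it. With the stage change of NIL(TGW6), which shares only its own 3 DAH levels and so can only be pulled down, r was -0.0772 (rank correlation 0.0642). Neither value is free of shared levels. At 6 DAH r was -0.273 and the rank correlation -0.0604, so both parts stay undecided, as does a different share of outer tissue, for which green pericarp markers stood 0.576 above aleurone and oil markers at 6 DAH. All measured markers passed the filter, which asks for 1 line at 1 stage, though some were undetected in whole groups, the brightest green gene (Os01g0600900, chlorophyll a-b binding) at levels of 16.6 and 16.9 at 3 DAH and 16.4 and 16.8 at 6 DAH, and 1 of 44 aleurone and oil markers is in another list too.

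Harvest or handling of the Nipponbare grains at 3 DAH may have raised the 900 genes at least 2-fold lower in NIL(TGW6) at that stage, and 48.2% of them (434) were at least 2-fold higher in Nipponbare at 3 DAH than in each of the other 3 groups, under the share predicted beforehand, while the arrays of the stage differed by a median of 0.0987 of the effect, also under the prediction but in genes whose choice favours arrays that agree. Of the 900, 503 were also called lower at 6 DAH, where 5719 of all 22710 genes were, and 126 by at least 2-fold, against 15.6 expected if the stages were independent. Of the 107 genes at least 2-fold lower on all 4 arrays, 57 lie on chromosomes 6 and 7. Probes there may pair poorly with the allele of the NIL, so the overlap does not bear on handling alone. From 3 to 6 DAH 462 of the 900 fell at least 2-fold in Nipponbare against 30 in NIL(TGW6). The 900 were chosen by the same 3 DAH levels, which favours falls in Nipponbare. That choice also largely fixes the comparison with NIL(TGW6) at 3 DAH within the 48.2%. An effect of the line stronger at 3 DAH would give the same values, and each line and stage may rest on a single harvest shared by both arrays, so these cannot be told apart. More outer tissue in the Nipponbare samples should lower the ratios of the markers of those tissues as far as the pattern's median of -1.66. Their lower quartiles were -0.639 (nucellus and maternal) and -0.403 (green pericarp), so most of these markers did not fall that far. That median comes from genes picked for falls of at least 2-fold, so it is a hard mark to reach. A smaller extra share of outer tissue is not excluded. At 3 DAH 5 nucellus and maternal markers were at least 2-fold lower and 0 higher, and 3 and 0 green pericarp markers. Tissues without markers are left open as well. Of the 32 nucellus and maternal markers, 1 is in another list too, and the brightest of them (Os02g0626100, phenylalanine ammonia-lyase) had levels of 15.7 and 15.9 at 3 DAH.

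Probes outside the comparisons also gave signal. Of 1020 spots of microRNA precursor probes, 73 (7.16%) were well above background in all channels, against 0 of 153 negative control spots and 0 of 240 spots of random and artificial probes.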

How the results depend on the processing

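The fits without chromosomes 6 and 7 and with a robust prior, the list patterns read without regard to case, and the list tests without background subtraction, on the series matrix values and under other scalings of the stage change were chosen after seeing the data. None of the single-gene, single-list or chromosome 6 results reversed. Of 1735 single-gene results, each gene counted again under every alternative, 1682 kept their side of the threshold. Many of these genes were picked for large changes past it, so genes of small change are little covered. Of 1568 single-list results 1475 kept their side. All 22 results for chromosome 6 did too. They were not repeated with the deposited processed signals, the series matrix values, no background subtraction or no filter on dim probes. The balance of the called genes did turn at 3 DAH. Most were lower in NIL(TGW6) here, and most were higher with the deposited processed signals. The median log2 ratio over all genes at 3 DAH was -0.0182 here and 0.0582 with those signals. With the deposited processed signals, genes at least 2-fold apart numbered 1810 at 3 DAH, 955 at 6 DAH, 2166 for the difference, 5165 for the stage change in Nipponbare and 3604 in NIL(TGW6). With the series matrix values they numbered 1767, 908 and 2068 for the first 3 of these. Over both stages 0 genes were called with either, without the filter on dim probes, or without chromosomes 6 and 7 (1787, 1835, 2337 and 1335 at an unadjusted p under 0.05, limma), so 0 of them were 2-fold. With the replicate block on all 4 arrays 95 were called, 83 at least 2-fold. Without that block 8700 genes were called at 3 DAH, 4519 at 6 DAH and 5435 for the difference. With loess within arrays alone 8024 were called in Nipponbare and 5129 in NIL(TGW6). A 2-fold minimum left 1056, 467, 1287, 3354 and 2043 genes for 3 DAH, 6 DAH, the difference, Nipponbare and NIL(TGW6), by its construction. Leaving out single arrays gave 5822 to 8908 genes at 3 DAH, 2283 to 6419 at 6 DAH, 3958 to 5956 for the difference, and 3 to 12 over both stages, all at least 2-fold. Lists past the test at 6 DAH then numbered 5 to 7. With an estimated correlation 0 lists passed for 3 DAH, 6 DAH, the difference or both stages, and 0 did at an unadjusted p under 0.05 (camera). There the correlation and the test rest on 1 residual degree of freedom. Hardly any list could pass, so these results do not check the preset test. For the other changes the cause was not tested. Median signals of 286.5 to 670.5 over backgrounds of 46 to 60 limit ratios of dim genes to lower bounds.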

Other observations

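The test of genes 2-fold on all 4 arrays was chosen after the result was seen, and the probe tests below before. Beyond the genes over both stages in the report, some genes on chromosome 6 near TGW6 in locus order were at least 2-fold lower on all 4 arrays without passing over both stages. The NADPH HC toxin reductase Os06g0651100, of a family that detoxifies a fungal toxin, was 3.07-fold lower in NIL(TGW6) at 3 DAH and 3.09-fold lower at 6 DAH (log2 -1.62 and -1.63, SE 0.058, n = 2). A bHLH gene (Os06g0653200) was 3.9-fold and 5.48-fold lower (log2 -1.96 and -2.45, SE 0.058), and a Zn-finger gene (Os06g0638000) 3.33-fold and 2.33-fold lower (log2 -1.74 and -1.22, SE 0.059).

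Genes of chromosomes 6 and 7 that were at least 2-fold lower in NIL(TGW6) on all 4 arrays numbered 57. Probes designed on Nipponbare may pair poorly with the allele of the NIL, or the transcripts may be lower there. Only 5 of the 57 genes have other probes, whose median log2 ratio was -1.44, and in 4 of the 5 (80%, exact interval 28.4% to 99.5%) all other probes were below -1. In Os06g0652400 the other probes had -0.262. With so few genes the explanations cannot be told apart.

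Genes at least 2-fold lower at both stages numbered 126, against 15.6 expected if the stages were independent, and those higher at both numbered 19 against 0.501. Overlaps in opposite directions were also above that expectation, with 25 genes higher then lower (2.71 expected) and 10 lower then higher (2.89 expected). The other probes without a locus ID were well above background in all channels in 32 of 350 spots (9.14%).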
